A study of Mus musculus with 12 samples.

How the data were processed

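The series holds m6A immunoprecipitation sequencing of livers of male C57BL/6 mice aged 12 weeks, after bile duct ligation (BDL) or without it. The labels list 3 BDL IP, 3 BDL input, 3 control IP and 3 control input samples. Per the labels' protocols, total RNA was fragmented, a part was kept as input, and the rest was enriched with an m6A antibody before reverse transcription with random primers. Per the submitters' processing notes the tools were bcl2fastq 2.17, fastp, Bowtie2 2.2.8 and HISAT2, without their roles. The peak caller, the rule for merging peaks, the read counter, its use of strand, the genome build and the annotation are not given in the sources used here.

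The deposited table gives, per the file headers, the raw read count of each of the 6 IP libraries in 1 set of merged peaks and the same values as RPM. The counts are whole numbers. The deposited RPM values are a score that equals each count divided by the library's total over the distinct peaks, scaled by a constant, and they were used only for this check. A peak annotated to several genes is listed once per gene with the same counts, so the 8649 lines hold 7460 distinct peaks. Only distinct peaks entered library sizes and tests. Peak starts count from 0 in the table, since 130 peaks start 1 base before the annotated gene start and 1 starts at it. Coordinates are given counting from 1, in the unnamed build of the deposited table. The gene positions listed there overlap those of the same symbol in a GRCm38.p6 gene table for 5270 of 5271 matched genes. No exon or untranslated region annotation was used, so a peak's place is given only along the gene span.

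The input libraries were not analysed here. The planned fits of expression, of IP over input, of the m6A difference corrected for expression, of both together, and of all 12 libraries were therefore not run, and the planned comparison of the IP libraries stands as the main one. IP reads mix transcript abundance and methylation.

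Peaks with low counts were removed with filterByExpr, libraries were scaled with TMM, and BDL was compared with control by edgeR's quasi-likelihood test (robust) with Benjamini-Hochberg adjustment and a threshold of 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. CPM values are TMM-normalised reads scaled to the library's reads in peaks, given as mean ± SD over 3 libraries. The SE of a log2 change is its size divided by the square root of the quasi-likelihood F. For genes, reads were summed over the peaks annotated to that gene alone, which held 6474 of the peaks. The other 986 entered only the tests of peaks. A group without reads was set to a floor of 3 reads in each library and the fold given as a bound. With 1 to 3 reads the ratio is given with an exact Poisson interval. The labels name no molecular identifiers, so intervals and floors cover counting error only. In every library more peaks had no reads than had 1 to 20 reads (422 against 60 in BDL replicate 1, 957 against 156 in control replicate 1). Zeros may therefore not all be counting zeros, and the bounds and intervals hold only where they are. The source of the zeros was not tested.

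Gene lists, 31 in all, were written before the data were examined, and 21 had at least 3 tested genes. Genes without a peak of their own or with low counts were not tested. A gene low in 1 group could enter through the other, so list values cover the tested genes only. They were tested with limma's camera on log2 values (prior count 2, correlation preset to 0.01), with an estimated correlation and with fry as alternatives. Lists with fewer tested genes were activated stellate cell (2), chemokines (2), neutrophil (1), B and plasma cell (2), mesothelium (1), cell cycle (2), and the erythroid, pancreatic acinar, mitochondrial and m6A eraser lists (0). Peaks of the same gene were compared with edgeR's diffSpliceDGE. Named peaks were, by a rule set before the data were examined, the 5 highest and 5 lowest log2 changes among peaks past the threshold whose BDL and control values did not overlap, whose mean level was above the median and whose gene is not a predicted model. The same rule named up to 4 members of each list with the smallest p and all writers and erasers. It was written for expression and was applied to the IP libraries after the columns of the table had been seen. Some peaks and genes that the rule picks are not reported here. Fosl2, Apob and Clec4f are named beyond it because they complete a count. Lists of male-biased and female-biased liver genes were written after the peaks with the largest changes had been seen.

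Alternatives set before the data were examined were DESeq2, its size factors in edgeR, library totals alone, no filter, at least 50 reads in every library of a group, an absolute log2 change of at least 1, each library left out in turn and the replicate number as a block. Alternatives added later were the gene as unit, peaks of 75 bases or less left out, libraries thinned to the smallest total or to the same median reads per peak, peaks of several genes counted for each, and all alternatives of the gene list, list pair and within-gene tests. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom from 142 to 219), so no library was counted as a duplicate. Spearman correlations across peaks were 0.908 to 0.922 within BDL, 0.877 to 0.903 within control and 0.762 to 0.827 between them.

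The steps were tested on simulated data drawn from the real means, dispersions and library sizes. With 200 of 7083 peaks changed, 5% of 2-fold and 35.4% of 4-fold changes were recovered, with 3 false among 43 calls. With 200 of 4306 genes changed, 18.4% and 56% were recovered, with 4 false among 78 calls. All 4 shifted lists were recovered by camera and 3 with an estimated correlation. Simulated genes were drawn independently, whereas the real lists that passed camera had estimated correlations from -0.031 (macrophage and monocyte) to 0.517 (endoplasmic reticulum stress). The simulation therefore cannot judge the preset correlation of 0.01. The within-gene test recovered 27 of 100 changed genes with 4 false calls. At this depth and number of libraries many 2-fold changes pass undetected.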

Results

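The study asked how RNA carrying N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, differs between livers with cholestatic fibrosis and healthy livers. Fibrosis was induced in male C57BL/6 mice by bile duct ligation (BDL), a surgical block of bile outflow, and normal mice served as controls, all aged 12 weeks. The 6 libraries analysed here were made from RNA fragments pulled down with an m6A antibody (IP), 3 from BDL and 3 from control livers. The unfractionated input libraries were not analysed here, so a difference in IP reads can come from the amount of a transcript, from its methylation, or from both. The libraries held 20540863, 35691860 and 26690519 reads in m6A peaks in BDL and 15254737, 19251404 and 19378332 in control. The counts covered 7460 merged peaks with a median width of 175 bases, and 64.4% of the peaks annotated to a single gene lay in the last 20% of the gene span. The labels number the samples without stating that each is a separate mouse, so edgeR and DESeq2 p-values measure the spread between these samples. Permutation tests over genes measure the spread between genes and not between samples.

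The m6A-IP profile of the liver differed widely between BDL and control. Peaks of Gpnmb, a transmembrane glycoprotein of activated macrophages, and of Ccr1, a chemokine receptor, rose in BDL from near background. A peak of Cldn4, a tight junction protein of bile duct epithelium, rose from a low level. Peaks of Slco1a1, a hepatocyte organic anion transporter, and Elovl3, a fatty acid elongase, almost disappeared. Of 7083 peaks tested, 649 passed the threshold, 327 higher and 322 lower in BDL (edgeR quasi-likelihood test, Benjamini-Hochberg). These peaks belonged to 582 genes or gene combinations, none of which had both a higher and a lower peak. With reads summed over the peaks of each gene, 635 of 4306 genes passed, 353 higher and 282 lower. The 3 BDL values lay entirely above or below the 3 control values for 37.4% of the tested peaks, where chance gives 10%.

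Among the peaks that rose most, Gpnmb (chromosome 6, 49047807 to 49047981) had 4540, 10157 and 6589 reads in BDL against 4, 2 and 6 in control, and its BDL level was 224 ± 27.3 CPM, the TMM-normalised reads scaled to the reads in peaks (mean ± SD, n = 3). Its log2 change was 9.78 (SE 0.39, edgeR adjusted p = 2.28e-05). The Ccr1 peak (chromosome 9, 123963249 to 123963423) rose by 9.34 (SE 0.77), with 2, 0 and 2 reads in control against 1017, 2609 and 1917 in BDL. Cldn4 (chromosome 5, 134945419 to 134946068) reached 1219 ± 286 in BDL against 11.3 ± 8.65 in control, a log2 change of 6.74 (SE 0.83). Ehf, an epithelial transcription factor (chromosome 2, 103264158 to 103264357), rose from 5.17 ± 4.42 to 166 ± 34.0 CPM (n = 3 each, edgeR adjusted p = 0.0251). Control replicate 2 held 2 reads of this Ehf peak while the other control libraries held 97 and 148.

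Among the peaks that fell most, Slco1a1 (chromosome 6, 141908807 to 141909006) had 10, 26 and 16 reads in BDL against 15658, 21657 and 19518 in control. Its log2 change was -11.06 (SE 0.25, edgeR adjusted p = 5.31e-07), the smallest adjusted p of all tested peaks. Elovl3 (chromosome 19, 46135095 to 46135319) fell from 756 ± 317 to 0.943 ± 1.02 CPM (n = 3 each), a log2 change of -9.74 (SE 0.87). A peak of Mup6, a major urinary protein gene (chromosome 4, 60004100 to 60005560), changed by -11.24 (SE 0.87). This value is uncertain because the Mup genes are near-identical copies that can share reads. A narrow peak of Nudt7, a peroxisomal hydrolase (chromosome 8, 114153222 to 114153296), kept 2 reads in BDL. Of peaks of 75 bases or less, such as this one and all those of Slc25a20, Ctsk, Mmp14, Cx3cr1, Cyp2d9 and Mup21, 14.3% had no reads in any of the 6 libraries, against 0.05% of wider peaks, so low counts in them are less certain. Control exceeded BDL by a ratio of 3952 for this peak (95% counting interval 1094 to 32632). Such intervals, and the bounds given below for groups without reads, hold only where absent reads are counting zeros. Of these 8 peaks, 7 passed in each fit that left out 1 library. The Ehf peak did not pass without BDL replicate 1, 2 or 3 or control replicate 1, where its adjusted p ranged up to 0.0964.

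**Figure D1:**
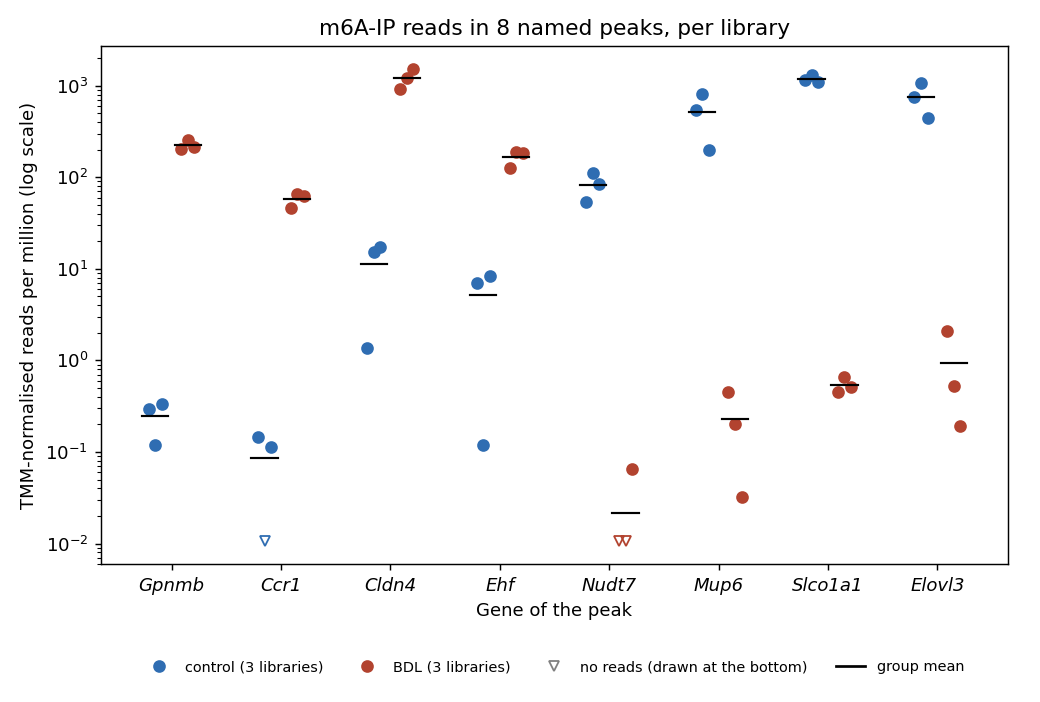
TMM-normalised IP reads in CPM (vertical log axis) in the 8 named peaks (horizontal axis), one circle per library, with black bars at group means over 3 libraries and open triangles for libraries without reads. The BDL and control libraries do not overlap for any of the 8 peaks, and Slco1a1 lies at 1182 ± 109 in control against 0.539 ± 0.104 in BDL.

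The total number of calls depended on single libraries. It fell from 649 to 338 without BDL replicate 1, to 155 without BDL replicate 2, to 170 without BDL replicate 3 and to 362 without control replicate 2. Scaling by library totals alone shifted the median log2 change of all peaks by 0.328 and called 608 peaks higher and 173 lower, so that 77.8% of calls were higher against 50.4% with TMM. DESeq2 called 1169 peaks, which included all 649. Of the 60 genes named here or among the further observations that passed at gene level, 33 passed in every fit that left out 1 library. The others, Fbln2, Ctsk, Mmp14, Loxl1, Pdgfra, Thbs1, Cyp2d9, Ttr, Serpinc1, Slc25a20, Cpt1a, Hp, Icam1, Cx3cr1, Cd5l, Il2rb, Wt1, Mcm3, Osgin1, Egr2, Klf6, Fosl2, Apob, Abcd2, Fmo2, Ntrk2 and Mup10, did not pass in at least 1 such fit, with edgeR adjusted p up to 0.199 (Loxl1, without BDL replicate 3), and none turned direction.

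Bile duct epithelium genes rose. Of 16 listed cholangiocyte genes, 7 had a peak and 6 were tested. Of these 6, 3 rose and none fell, with a median log2 change of 4.49. Ehf went from 10.6 ± 2.67 to 339.8 ± 73.2 CPM summed over its 2 peaks (n = 3 each). Cd24a, a surface glycoprotein, rose by 3.99 on the log2 scale (SE 0.43), and Cldn4 by 6.73 (SE 0.80). Cftr, a chloride channel, had a log2 value of 5.01 (SE 1.58) that did not pass (edgeR adjusted p = 0.0717). It passed in 1 of the 6 fits without 1 library, that without control replicate 2 (8.91e-04), while the others gave up to 0.166 and DESeq2 0.186. Adjusted over the list alone, 5 of the 6 rose. The list passed limma's camera test (adjusted p = 0.00295 over 21 lists), with adjusted p = 0.343 with an estimated correlation.

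Macrophage and monocyte genes rose as well, 4 of 6 tested out of 16 listed, with a median log2 change of 2.98. Gpnmb rose by 9.76 on the log2 scale (SE 0.38). Cd14, a lipopolysaccharide co-receptor, went from 291 ± 248 to 2619 ± 608 CPM (n = 3 each). The fractalkine receptor Cx3cr1 rose by 6.67 (SE 1.34) and the Kupffer cell gene Cd5l by 0.90 (SE 0.24). Adjusted over the list alone, 5 rose and 1 fell. The one that fell was Clec4f, also a Kupffer cell gene. Its log2 value was -0.60 (SE 0.24, edgeR adjusted p = 0.0386 over the list and 0.147 over all genes). The list passed camera (adjusted p = 0.00938; adjusted p = 0.343 with an estimated correlation). Without peaks of 75 bases or less, which removed Cx3cr1 and left 5 genes, its median was 2.78 and it did not pass (0.0618). Of 4 T and NK cell genes, Il2rb, an interleukin-2 receptor chain, rose at least 43.1-fold from no reads in control. That list did not pass (adjusted p = 0.0624), except without BDL replicate 3 (0.0493) or control replicate 1 (0.0288). None of 7 endothelial genes passed edgeR, with 1 at an unadjusted p under 0.05 and 0 with DESeq2. Among them Cdh5 had a log2 value of 0.68 (SE 0.24) and Tek of -1.17 (SE 0.64). Cdh5 passed edgeR with library totals alone (log2 0.95, adjusted p = 0.0296) and without control replicate 1 (0.0235), while the other fits without 1 library gave up to 0.297.

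Genes of the fibrotic matrix rose in the BDL livers. The fibrillar collagen gene Col5a2 went from 25.2 ± 2.56 to 170.5 ± 37.4 CPM (n = 3 each). Fibrillin gene Fbn1 rose by 2.77 on the log2 scale (SE 0.35) and Fbln2 by 2.30 (SE 0.49). These were 3 of 5 tested genes of the fibrillar and basement membrane matrix list, which had 20 members. The median log2 change of the tested genes was 2.30 (camera adjusted p = 0.00717, and 0.347 with an estimated correlation). Of 5 tested matrix remodelling genes, out of 18 listed, 3 rose, and all 5 did when adjusted over the list alone. Ctsk, a collagen-degrading cathepsin, rose at least 85.7-fold from no reads in control, the membrane metalloproteinase Mmp14 rose by 1.69 on the log2 scale (SE 0.33) and Loxl1, a collagen and elastin crosslinking enzyme, rose 4.51-fold. That list passed camera (adjusted p = 0.0031; adjusted p = 0.343 with an estimated correlation). Without peaks of 75 bases or less, which removed Ctsk and Mmp14 and left 3 genes, its median was 2.06, against 2.07 with them, and it did not pass (0.0669). The stellate cell receptor Pdgfra rose by 1.35 (SE 0.30). Pdgfrb had a log2 value of 0.92 (SE 0.28) that did not pass over all genes (edgeR adjusted p = 0.060). It passed when adjusted over the list alone (0.00966), with DESeq2 (0.0287) and with library totals alone (0.0211), and in none of the fits without 1 library (0.0570 to 0.195).

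Of 11 TGF-beta pathway genes, 2 rose and none fell. Connective tissue growth factor, Ccn2, went from 52.0 ± 11.5 to 359 ± 103 CPM (n = 3 each), and thrombospondin Thbs1 rose by 3.78 on the log2 scale (SE 1.03). The list did not pass camera (adjusted p = 0.0625), except without control replicate 1 (0.0288). Immediate early genes, which respond quickly to stress and growth signals, rose as a list, 5 of 13 tested. The list had 17 members, and the median log2 change of the tested ones was 1.45. The transcription factors Atf3 (2.31, SE 0.31), Jun (1.45, SE 0.22), Klf6 (2.69, SE 0.61) and Fosl2 (1.95, SE 0.47) rose. Egr2 also rose, with 2 reads in control and a ratio of 286 (95% counting interval 79.2 to 2362). Adjusted over the list alone, 6 rose, and camera gave adjusted p = 0.00145 (adjusted p = 0.343 with an estimated correlation).

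Genes of protein folding in the endoplasmic reticulum fell. Of 6 tested genes of the endoplasmic reticulum stress list, out of 16 listed, 4 fell and none rose, with a median log2 change of -1.31. The chaperone gene Hspa5 went from 28024 ± 4262 to 11800 ± 1471 CPM (n = 3 each). Manf fell by 1.74 on the log2 scale (SE 0.19), Dnajb9 fell by 1.77 (SE 0.26) and the transcription factor Xbp1 fell by 1.36 (SE 0.23). The list passed camera (adjusted p = 0.00938; adjusted p = 0.384 with an estimated correlation).

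Fatty acid oxidation genes fell, 3 of 9 tested out of 18 listed, with a median log2 change of -0.91. The carnitine carrier Slc25a20 was at least 96.1-fold lower, with no reads in BDL, and Cpt1a fell by 0.91 on the log2 scale (SE 0.22). The camera call (adjusted p = 0.0261; adjusted p = 0.362 with an estimated correlation) was lost without peaks of 75 bases or less (0.214, median -0.59 over the 6 genes left), without BDL replicate 3 (0.0646) and without control replicate 1 (0.0570). The lipid-sensing receptor Ppara fell by 1.73 (SE 0.18), 1 of 7 bile acid receptor and regulator genes to pass.

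In bile acid handling, 2 transport genes and 1 synthesis gene fell. The bile acid uptake transporter Slc10a1 went from 3702 ± 733 to 1074 ± 267 CPM (n = 3 each). With Slco1a1 it made up the 2 of 6 transport genes that fell (camera adjusted p = 0.0625, and 0.0292 without BDL replicate 1). Amacr, a racemase of bile acid side chain synthesis, fell by 1.06 on the log2 scale (SE 0.18), 1 of 5 synthesis genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 value of 0.54 (SE 0.78, edgeR adjusted p = 0.709). Of 6 xenobiotic cytochrome P450 genes, Cyp2j5 fell by 1.70 (SE 0.17) and Cyp2d9 fell by 3.01 (SE 0.67).

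Hepatocyte genes fell in part. Of 12 tested genes of secreted and metabolic hepatocyte products, 5 fell and none rose, and the list did not pass camera (adjusted p = 0.191). Apolipoprotein gene Apoa2 went from 1603 ± 304 to 509 ± 23.7 CPM (n = 3 each). The transcription factor Cebpa went from 2022 ± 172 to 717 ± 111. The transthyretin gene Ttr fell by 1.36 on the log2 scale (SE 0.30), Serpinc1 fell by 0.78 (SE 0.19) and Apob fell by 0.59 (SE 0.16). Acute phase genes went both ways. C-reactive protein, Crp, went from 59070 ± 1486 to 21609 ± 912 and Saa4 fell by 2.50 (SE 0.37), while haptoglobin, Hp, rose by 0.69 (SE 0.19). The sterol regulator Insig1 fell by 1.37 (SE 0.25), 1 of 9 cholesterol synthesis genes, and Osgin1 fell by 0.96 (SE 0.27), 1 of 4 oxidative stress genes. Under scaling by library totals alone, Serpinc1, Apob, Cpt1a and Osgin1 no longer passed, with edgeR adjusted p from 0.0774 to 0.204. The lists of bile acid synthesis (camera adjusted p = 0.298), bile acid receptors (0.298), xenobiotic cytochromes (0.174), cholesterol synthesis (0.415), acute phase (0.380), oxidative stress (0.718), endothelium (0.718), m6A writers (0.238), m6A readers (0.298) and ribosomal proteins (0.718) did not pass. None of the 6 ribosomal protein genes passed edgeR, with 0 at an unadjusted p under 0.05 and 0 with DESeq2.

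None of 11 tested m6A machinery genes passed edgeR over all genes. These were 5 of 11 listed writers and 6 of 18 listed readers, so most of the listed machinery was not tested. At an unadjusted p under 0.05 there were 3, and DESeq2 called 2, the readers Ythdc1 and Ythdf3. Adjusted over the 11 machinery genes alone, 0 passed edgeR. Adjusted over the narrower reader list alone, Ythdc1 and Ythdf3 were the 2 of 6 readers that passed (edgeR, each 0.0425), 1 higher and 1 lower in BDL. None of 5 writers passed when adjusted over their list. The writers list holds genes of enzymes that add the mark and of their partner proteins. Log2 values were -0.75 for Rbm15 (SE 0.38), -0.27 for Wtap (SE 0.17), -0.64 for Zc3h13 (SE 0.45), -1.15 for Mettl16 (SE 0.89) and 0.11 for Virma (SE 0.21). No other listed writer was tested. The value of Wtap turned to 0.00501 under scaling by library totals alone. Ythdc1 had a log2 value of 0.88 (SE 0.26, edgeR adjusted p = 0.0519) and Ythdf3 of -0.44 (SE 0.14, 0.0782). Ythdc1 passed edgeR with library totals alone (log2 1.16, adjusted p = 0.0188), with DESeq2 size factors (0.0496) and without peaks of 75 bases or less (0.0424), and in none of the fits without 1 library (0.0575 to 0.212). No peak was annotated to either eraser gene, the enzymes that remove the mark. These are IP reads of the transcripts and do not measure the enzymes.

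**Figure D2:**
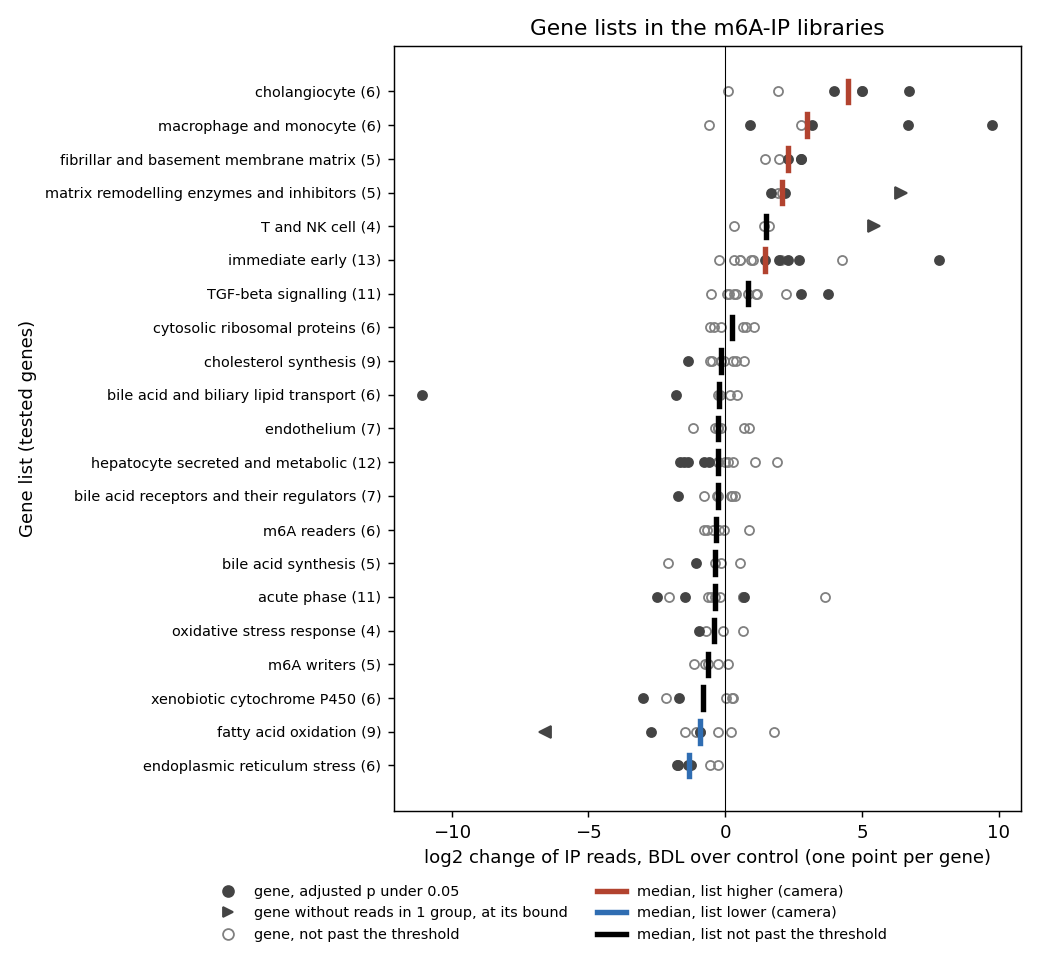
Log2 change of IP reads, BDL over control (horizontal axis), for each tested gene of 21 gene lists (vertical axis, tested genes in brackets), with filled circles for genes past the edgeR threshold, open circles for the others, triangles at the bound for genes without reads in 1 group and bars at list medians. The cholangiocyte list has the highest median, 4.49, and the endoplasmic reticulum stress list the lowest, -1.31.

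Peaks of the same gene were compared with each other to look for changes beyond those of the whole transcript. A differing peak does not by itself show a change in methylation, since the amount of each part of a transcript was not measured here. Of 1288 genes with at least 2 tested peaks, 13 had peaks that changed by different amounts (edgeR diffSpliceDGE, Benjamini-Hochberg). Smoc2, a matrix protein, had 1 peak with 3226 reads in BDL and 4 in control (chromosome 17, 14403651 to 14403775) and another that rose by 2.91 on the log2 scale (SE 0.29). In Enc1, an actin-binding protein, 1 peak had 4570 reads in BDL and 2 in control (chromosome 13, 97250723 to 97250872), while the least changed of its 3 peaks rose by 2.22 (SE 0.32). In Nudt7, the least changed of 5 peaks fell by 4.51 (SE 0.28), against the near loss of the narrow peak given above. Masp1, a complement protease, had a peak with 848 reads in control and 0 in BDL (chromosome 16, 23479666 to 23479840) beside one at a log2 value of 0.18 (SE 0.22). Of the 13 genes, 9 had a peak with 0 reads in one condition, as did Masp1. These 4 genes were chosen after their values were seen. The count went from 13 to 4 without BDL replicate 1, to 1 without BDL replicate 2, to 1 without BDL replicate 3, to 33 without control replicate 2 and to 8 with no low-count filter.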

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

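The tests with peaks of 75 bases or less left out, with thinned libraries, with shared peaks and of the gene list and within-gene alternatives were chosen after the data were seen. Of 649 peaks past the threshold, DESeq2 called all among its 1169 (640 higher, 529 lower). Library totals alone called 608 higher and 173 lower, the scaling alone being the difference. Leaving out 1 library gave 155 to 611 peaks (73 to 370 higher, 82 to 241 lower), 223 to 622 genes, 7 to 8 lists, 1 to 33 genes with peaks that differ, 114 to 194 peaks with reads in all BDL and no control library and 25 to 49 in all control and no BDL library. Fewer samples lower the power of these fits. Of the 60 named genes past the threshold, 33 passed in all 6 such fits and 27 did not in at least 1, none reversing. Without peaks of 75 bases or less, 4 lists passed in place of 7, and 10 peaks in place of 23 had reads in all control and no BDL library. With no low-count filter 8 genes in place of 13 had peaks that differ. For m6A machinery genes, 0 in the main test, the count was 2 with DESeq2 and 1 each with its size factors in edgeR, library totals alone and narrow peaks left out. No list passed with an estimated correlation, with 1 at an unadjusted p under 0.05, and 13 passed with fry. The macrophage and monocyte list had an estimated correlation of -0.031, below the preset 0.01. Its camera adjusted p still went from 0.00938 to 0.343, so a higher correlation of its members did not cause that loss. The cause of these differences was otherwise not tested.

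Same-numbered BDL and control libraries are not paired by the labels, and their deviations correlated by only 0.03, 0.01 and 0.01. With the replicate number as a block, 287 peaks (144 higher, 143 lower), 415 genes and 0 genes with peaks that differ passed. Of the 287, 272 were among the 649.

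Values that changed sign were medians and levels near 0, none past the threshold. With library totals alone these were Wtap (0.00501) and the medians of bile acid transport (0.0506), bile acid receptors (0.00576), cholesterol synthesis (0.111) and endothelium (0.0235). Without narrow peaks the ribosomal protein median was -0.397. Over the fits without 1 library the medians ranged from -0.277 to 0.0723 for cholesterol synthesis, -0.468 to 0.0110 for bile acid synthesis, -0.683 to 0.217 for acute phase, -0.701 to 0.0665 for oxidative stress and -0.0282 to 0.678 for ribosomal proteins. The authors' peak threshold, 1-base against reciprocal overlap, and fits needing input libraries were not run.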

Other observations

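The tests of male-biased genes, of pairs of cell type lists and of depth were chosen after results had been seen. The list of female-biased genes was written after the largest peak changes were seen and before any value of its own members. Among lists too small to test as sets, the adhesion molecule Icam1 rose from 711 to 1302 CPM and the replication gene Mcm3 from 25.3 to 63.1. Neither B and plasma cell gene and not the neutrophil gene passed edgeR, at an unadjusted p under 0.05 or with DESeq2. Wt1, a mesothelial transcription factor, had 2 reads in control and a BDL ratio of 227 (95% counting interval 62.8 to 1874). Peaks with reads in all 3 BDL and no control library numbered 104, and 23 showed the reverse. Libraries thinned to 15254737 reads gave 106 and 24. Thinned to the same median reads per peak, where BDL libraries held fewer reads than control libraries, they gave 105 and 23. The merged peaks were fixed before thinning, and thinning adds no reads to control. An effect of depth on which peaks were called therefore stays open.

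Male-biased liver genes were lower in BDL. All 12 tested members of a list of 32 fell, with a median log2 change of -6.58 (-5.71 with bounds for members without reads). Besides Slco1a1, Elovl3, Nudt7 and Cyp2d9 these included Ugt2b1 (-4.24, SE 0.26), Sdr9c7 (-4.60, SE 0.45) and Susd4 (-3.03, SE 0.34), and 4 Mup genes that can share reads. The list is not independent evidence, since 9 of its 12 tested members had been seen among the largest falls when it was written. The other 3, Mup10, Mup21 and Fitm1, lay below 12 hepatocyte genes (exact one-sided permutation test over genes, p = 0.0022), but only Fitm1 is outside the Mup family. The hepatocyte genes, from a list written before the data were examined, had a median of -0.267 (SD 1.05, from -1.66 to 1.88). All lay above the smallest fall of the male-biased list, -2.63 in Fitm1. That gap is no test, since 9 male-biased members were listed after their falls were seen. The hepatocyte values themselves show no fall as large, which argues against a general loss of hepatocyte transcripts as the whole cause. The hepatocyte median was -0.625 without BDL replicate 1, -0.145 without BDL replicate 3 and -0.562 without peaks of 75 bases or less. With library totals alone it was -0.000143 and the male-biased median -6.31. A shift from a male to a female programme is a candidate explanation. No female-biased gene had been seen beforehand. Of 30 listed, 7 were tested and had a median log2 change of 1.72, above level-matched random genes (one-sided permutation test over genes, p = 0.0026). Abcd2 (2.13, SE 0.52), Fmo2 (4.59-fold) and Ntrk2 (5.52, SE 1.42) rose. Whether these transcripts came from hepatocytes was not tested.

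The non-hepatocyte lists that rose could reflect a lower share of hepatocytes alone, which would raise every other cell type alike. The test set beforehand, over the medians of the cholangiocyte, macrophage, T and NK cell and endothelium lists, gave p = 0.176 (permutation test) and left this open. Once the medians had been seen, pairs of lists were compared. The cholangiocyte mean log2 change was 3.80 (SD 2.39 over 6 genes) and the endothelium mean -0.09 (SD 0.68 over 7 genes), which differ at p = 0.0105 (exact permutation test, two-sided, adjusted over all 6 pairs of the 4 lists). The macrophage and monocyte list and the T and NK cell list also lay above endothelium (adjusted p = 0.0198 each), and the other 3 pairs gave 0.989. Without peaks of 75 bases or less the macrophage pair did not pass (0.0606, with 5 against 6 genes and a difference of 3.28 in place of 3.88). These tests shuffled genes as if independent, so their p-values measure the spread between genes, not between samples. After the values were seen, a pair was also required to differ by more than the larger SD of its lists. The cholangiocyte pair did (3.89), which argues against a lower hepatocyte share as the whole cause of the rise of these 6 genes. The macrophage pair did so only narrowly (3.88, SD 3.82), so a lower share stays open there. It also stays open for T and NK cells, whose mean of 3.49 (SD 4.77 over 4 genes) rests on Il2rb, without reads in control. A change in each cell type or its number stays open too.

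Peaks of the same gene mostly moved together. In all 51 genes with at least 2 peaks past the threshold the peaks went the same way, and the intraclass correlation of log2 changes was 0.501 (95% bootstrap interval 0.426 to 0.567) over 1288 genes. It was 0.814 (0.740 to 0.872) among peaks above the median level and 0.439 (0.335 to 0.553) between the first and last peaks of 714 genes where these lay over 1000 bases apart. Transcript abundance may produce this, but so would methylation changing along the whole gene, and the interval spans the bound set beforehand, so these cannot be told apart without input libraries. For the 13 genes with peaks that differ, the higher peak lay nearer the 3' end in 30.8% (exact binomial test, p = 0.267, 95% interval 9.09% to 61.4%), too few genes to judge a bias from RNA quality.

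Other splits of the 6 libraries, 3 against 3, number 10 with the real one, too few for a share under 0.05. Only 1 split, the real one, gave as many peaks (649, highest other 0), genes (635, highest other 0), lists (7, highest other 4) and genes with peaks that differ (13, highest other 0).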
